A study of Mus musculus with 4 samples.

How the data were processed

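Total RNA of the mouse dentate gyrus was measured on 4 Affymetrix-type oligonucleotide arrays, 1 each at 1, 2, 4 and 6 h after the last of 3 shocks, per the labels. The deposited values are intensity values, 1 per probe set on a linear scale, all above 0 with 1 decimal. The image analysis, the summary of probes into probe sets and the scaling that the authors used are not given in the sources used here. The deposited intensity values had a 2% trimmed mean of 500.3 on each array over 12488 probe sets, so the arrays had been scaled to a common target before deposit, as read from the values. The submitters' labels share an ordinal in the titles that is not explained, and it was not read as a replicate number. Detection calls and scanner files were not used here.

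The 66 control probe sets were set aside, which left 12422. Each array was rescaled by its 2% trimmed mean (factors of 0.998 to 1.001), values below the pooled 40th percentile (126 intensity units) were raised to that floor, and log2 was taken. Ratios against a signal under the floor are lower bounds on the fold and are written as such. Gene names came from the platform annotation supplied as a probe table, where 10833 analysed probe sets had 1 gene symbol, 396 several and 1193 none, and probe sets with several were not named. Of the named probe sets 10817 were found by gene identifier in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. The files name no genome build, so no coordinates are given. A gene was represented by its probe set of highest mean signal (8251 genes), and counted as measured when it reached the floor on at least 1 array (6567 genes). Every value column was matched to a sample by its heading.

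With 1 array per time point no test between 2 times could be made. After the data had been seen, a linear trend on hours over all 4 arrays was fitted to the log2 values of probe sets above the floor on every array (limma's lmFit and eBayes, 2 residual degrees of freedom, Benjamini-Hochberg adjustment), and its p-values describe these 4 arrays. A difference was counted where the floored values of a pair of arrays differed by at least 2-fold. A probe set stood apart when it lay at least 2-fold above or below all other arrays, and a steady course needed the same direction at each step, a signal above the floor on all arrays, and at least 2-fold from 1 to 6 h. Before the data were examined, 26 gene lists were fixed, covering activity-regulated genes, hormone and stress responses, clock, cholesterol, synaptic, kinase, chromatin, respiratory, ribosomal and proteasome genes, and markers of the cell types and neighbouring tissues that a dissection can include. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 10 bins, and stood outside when it lay outside the central 95% of their medians with at least 5 measured genes, which 25 lists had. Of 459 measured list genes 12 are in more than 1 list, and genes of a list are not independent, so the percentile describes these arrays. The named genes also followed a rule fixed before the data were examined. For each of 2, 4 and 6 h against 1 h, it took the 10 genes with the largest and the 10 with the smallest ratio above the floor on both arrays and past 2-fold, then the 5 largest in each direction with a steady course, any immediate early gene, and the 2 to 4 members of each other list with the largest absolute ratio in the comparison described (over all 3 where a list is described across them), leaving out symbols that are only clone or locus names. The genes followed between successive times were picked from those already named, after their values were seen, and Bdnf was named outside the rule.

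Scatter was gauged from genes with at least 2 probe sets above the floor. The SD of the difference between their log2 ratios, divided by the square root of 2, was 0.53 at 2 h, 0.46 at 4 h and 0.40 at 6 h, all against 1 h. In 100 simulations per comparison, ratios drawn from those differences with random sign, by level of signal, were added to otherwise equal arrays and the differences of at least 2-fold counted. Probe sets of a gene can also differ through transcript variants, so this scatter is not pure measurement noise, and noise shared by the probe sets of an array is not in it. It was gauged above the floor but applied to all probe sets, so it may not hold for signals under the floor.

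Settings chosen in advance and tried in place of the main ones were the deposited scale, quantile normalization, cyclic loess of the floored values (what lay above the floor was read before it), floors at the 20th and 60th percentile, thresholds of 1.5-fold and 3-fold, and the median over all probe sets of a gene. Chosen after seeing the data were leaving out the 2 h array, the mean of the 3 other arrays as the reference, the choroid plexus list without Ttr, and random lists matched on gene length as well (5 bins each of length and signal; 99.9% of genes had a length, the genomic span). The counting and list steps were tested on simulated data. For 2 h against 1 h with a noise SD of 0.3, 200 probe sets with a mean signal over 4-fold above the floor were changed 4-fold. Of these 99.5% were recovered, 0 in the wrong direction, and 5 of the unchanged probe sets among 12422 were called. Of 200 random lists of 20 genes 4.0% fell outside the range, and all 100 lists shifted by 0.3 did. For the linear trend over 6109 simulated probe sets with that noise, all 200 that changed 4-fold from 1 to 6 h and 6 unchanged ones passed the adjusted threshold of 0.05. The simulated noise was below the scatter gauged on these arrays (0.53, 0.46 and 0.40 at 2, 4 and 6 h against 1 h). These simulations therefore check the steps and do not measure recovery or false calls on these arrays. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for quantile normalization, cyclic loess and the linear trend.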

Results

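Gene expression was measured in the dentate gyrus, the hippocampal subfield whose principal cells are the granule neurons, of young male C57BL/6J mice, an inbred laboratory strain, after contextual fear conditioning. In this protocol an animal spends 2 min in an unfamiliar chamber and then receives a foot shock of 0.5 mA lasting 1 s, and the cycle runs to 3 shocks in all. Total RNA was taken 1, 2, 4 or 6 h after the last shock and 1 oligonucleotide array was hybridised for each time, which makes 4 arrays of 12488 probe sets (groups of short probes directed at a transcript). Unconditioned animals were not analysed here, so each comparison asks how a later sample differed from an earlier one, not how conditioned animals differed from resting ones. The number of animals behind an array is not given in the sources used here. With 1 array per time point no value has a replicate error and no difference between 2 times could be tested, so every difference describes these arrays. The number of arrays limits the precision of every value. Between 58.3% (1 h) and 62.1% (4 h) of the probe sets lay at or above the floor of 126 intensity units. Log2 intensities correlated across probe sets above the floor on both arrays at Pearson's r of 0.936 (2 h with 1 h), 0.950 (4 h with 1 h) and 0.964 (6 h with 1 h), where probe sets are not independent replicates.

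At 2 h, the presynaptic and the postsynaptic gene list lay above their 1 h level, with 7 of 20 and 7 of 16 measured members at least 2-fold higher (median log2 ratios 0.50 and 0.51). Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, lay below it, with 4 of 9 at least 2-fold lower (-0.97). Kif5a, which encodes a neuronal kinesin heavy chain, had the highest ratio among genes above the floor on both arrays and read 1339.9 at 2 h and 144 at 1 h, a 9.33-fold difference (log2 ratio 3.22). Kif1a, the kinesin that carries synaptic vesicle precursors along axons, read 791 and 129, a 6.11-fold difference. Ttr, the thyroxine carrier transthyretin and a leading transcript of choroid plexus epithelium, read 217 at 2 h and 5228.5 at 1 h, which was 24.1-fold lower at 2 h. Of 12422 probe sets, 441 were at least 2-fold higher and 166 at least 2-fold lower at 2 h.

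The other genes furthest above their 1 h level at 2 h included Rnf112, a brain-enriched RING finger GTPase (log2 ratio 2.43), and Nnat, the imprinted neuronal proteolipid neuronatin (2.34). Grik5, a kainate-type glutamate receptor subunit, was higher by 2.24 and by 0.65 on its other probe set. Lin7b, a scaffold of synaptic and epithelial membranes, differed by 2.17, Atp6v0a1, a subunit of the vesicular proton pump, by 2.03, and the synaptotagmin Syt11 by 2.02. Rrp1, a nucleolar factor of ribosomal RNA processing, stood at 2.23 and the proline-rich protein gene Prp2 at 2.39. Among genes above the floor on both arrays, the lowest ratio after Ttr was that of Tradd, the adaptor of the tumour necrosis factor receptor (log2 ratio -2.36). Sema4b, a transmembrane semaphorin, followed at -1.82, with 0.39 on the only other of its probe sets above the floor. The lysine methyltransferase gene Smyd2 stood at -1.70. The phosphatase gene Phospho2 stood at -1.66, Kcnd2, the A-type potassium channel Kv4.2, at -1.57, and Smo, the hedgehog signal transducer, at -1.50. Limk1, the kinase of cofilin, stood at -1.50 with -0.13 on its other probe set, Scp2, a sterol carrier, at -1.50 with -0.31 on its other probe set, and the deubiquitinase gene Usp1 at -1.49. Smo (127), Phospho2 (129) and Usp1 (136) read close to the floor at 2 h. The probe sets of Kif5a, Nnat, Prp2, Tradd, Sema4b, Kcnd2 and Limk1, and further on those of Vamp1, Glul, Cox6b2, Rps13, Ddx6, Dab1, Pcp2, Polr3k, Sc5d, Acvrl1, Thyn1, Atf3, Zfp36, Junb, Tdo2, Pvalb, Ptgds and Eif2s3y, carry identifier suffixes that mark probes shared with other transcripts or chosen under relaxed rules.

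Both synaptic lists fixed in advance lay above all 10000 random lists of the same size and matched signal at 2 h, where the central 95% of the random medians is called the random range. The 20 measured presynaptic vesicle genes had a median log2 ratio of 0.50, with 7 members at least 2-fold higher, 0 at least 2-fold lower and 13 within 2-fold. Of these genes 14 lay above and 6 below 0. Syt1, the calcium sensor of transmitter release, read 2456 at 2 h and 695 at 1 h (3.53-fold), and Cplx1, a complexin that clamps vesicle fusion, 3053 and 905 (3.37-fold). Vamp1, a vesicle SNARE protein, was at least 3.56-fold higher, since its 1 h signal lay under the floor. The 16 measured glutamate receptor and postsynaptic genes had a median of 0.51, with 7 at least 2-fold higher, 0 at least 2-fold lower and 9 within 2-fold. Of these 11 lay above and 4 below 0. Grin2b, an NMDA receptor subunit, was at least 5.0-fold higher from a 1 h signal under the floor, the AMPA receptor subunit gene Gria3 was 3.19-fold higher (452 and 142), and Dlg4, which encodes the scaffold PSD-95, was 2.70-fold higher (1079 and 399.8). The 2 h array also stood apart in its technical controls. The ratio of 3' to 5' signal of Gapdh, a housekeeping enzyme probed along its transcript, was 1.26 at 2 h against 4.31 at 1 h, 5.25 at 4 h and 3.78 at 6 h. For Actb, the beta-actin control, it was 1.55 at 2 h against 2.56, 2.54 and 2.62. The 9 hybridisation spike-in probe sets (added bacterial and phage transcripts) had a median log2 ratio of -0.69 at 2 h against 1 h, compared with 0.31 at 4 h and 0.06 at 6 h. The 3' probe set of 18S ribosomal RNA read 2317 at 2 h and 1530.1 at 1 h.

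**Figure D1:**
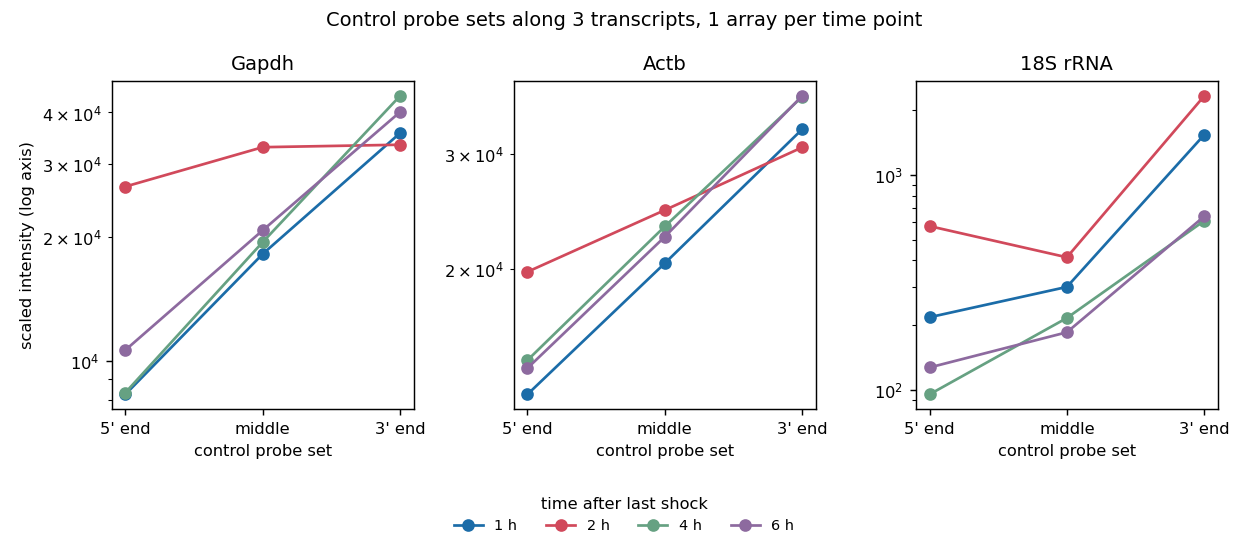
Scaled intensity (log axis) of the control probe sets at the 5' end, middle and 3' end of Gapdh, Actb and 18S ribosomal RNA, with 1 line per array. The 2 h array had a Gapdh 5' signal of 26438 where the 1, 4 and 6 h arrays had 8278, 8357 and 10602.

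Markers of cell types that a dissected dentate gyrus can include also differed at 2 h. Choroid plexus markers (9 measured) had a median log2 ratio of -0.97, below all 10000 random lists, with 4 members at least 2-fold lower, 0 higher and 5 within 2-fold. Besides Ttr, these were Kl, the ageing-related membrane protein klotho (at least 4.02-fold lower), Folr1, the folate receptor (at least 2.38-fold lower), and Ace, the angiotensin-converting enzyme (at least 2.06-fold lower), each under the floor at 2 h. The 8 CA field and mossy cell markers label hippocampal neurons other than granule neurons. They had a median of 0.40 (percentile 98.6 of the random lists), with 2 at least 2-fold higher, 0 lower and 6 within 2-fold. Calb2, the calcium buffer calretinin (1.07), and Dkk3, a secreted Dickkopf family protein (1.00), led the list. The 10 thalamus and habenula markers had a median of 0.52 (percentile 98.8), with 3 at least 2-fold higher and 0 lower. Lef1, a transcription factor of the Wnt pathway, was at least 5.92-fold higher and the zinc finger gene Zic2 at least 2.27-fold higher, both from 1 h signals under the floor. The 15 astrocyte markers had a median of 0.27 (percentile 98.4), with 1 at least 2-fold higher, Atp1b2, the beta-2 subunit of the sodium pump (1.49), 0 lower and 14 within 2-fold. Glul, glutamine synthetase, stood at 0.74.

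Genes of mitochondrial respiration and of protein synthesis lay lower at 2 h, by smaller amounts. The 63 measured oxidative phosphorylation genes had a median log2 ratio of -0.31 (percentile 0.03), with 47 below and 14 above 0, 2 at least 2-fold lower and 0 higher. Ndufab1, the acyl carrier subunit of complex I, read 1575 at 2 h and 3682 at 1 h (-1.22), and Cox6b2, a cytochrome oxidase subunit, was at least 2.36-fold lower. The 29 cytosolic ribosomal protein genes had a median of -0.30 (percentile 0.78), with 1 at least 2-fold lower, Rps13 (-1.02), 0 higher and 28 within 2-fold, among them Rps29 at 0.72. The 12 measured targets of the inflammatory transcription factor NF-kappa B had a median of -0.53 (percentile 0.07), with 3 at least 2-fold lower, 0 higher and 9 within 2-fold. These 3 were Gadd45b, a stress-inducible growth arrest gene (-1.40), Relb, an NF-kappa B subunit (at least 2.28-fold lower), and Vcam1, an adhesion molecule (-1.12).

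Simulated array pairs differed only by the scatter between probe sets of the same gene. They gave a mean of 417 differences of at least 2-fold (378 to 463 in 100 simulations), against 607 observed between 2 and 1 h. Of these 607, 303 higher and 112 lower had both arrays above the floor, where the scatter was gauged. The simulated counts cover all probe sets, those under the floor included, so there is no simulated count for those above it. Whether the excess goes beyond scatter therefore stays open, here and at 4 and 6 h. Presynaptic, postsynaptic, oxidative phosphorylation and choroid plexus lists stayed outside the random range under all 6 processing settings tried besides the main one, whereas the NF-kappa B (4 of 6), ribosomal protein (2 of 6), CA field (4 of 6), thalamus (3 of 6) and astrocyte (5 of 6) lists kept their place in only some. These settings reuse the same 4 arrays, and the deposited scale among them is nearly the main one (factors of 0.998 to 1.001). Against the mean of the other arrays, oxidative phosphorylation (-0.16, percentile 10.2), ribosomal protein (-0.11, percentile 38.0), CA field (0.12, percentile 84.3) and thalamus (0.27, percentile 92.4) medians fell inside the range.

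At 4 h, the cholesterol synthesis, choroid plexus and myelin lists lay below their 1 h level (median log2 ratios -0.41, -0.73 and -0.23) and 0 lists lay above the random range. Btbd3, a BTB domain protein that orients dendrites, had the highest ratio among genes above the floor on both arrays. It read 1753.5 at 4 h and 357 at 1 h, a 4.91-fold difference (log2 ratio 2.30). Its 2 h reading was already 1240, and it stood below all other arrays at 1 h. Ntrk3, the receptor for neurotrophin-3, was 3.67-fold higher (1.87), and Dab1, the adaptor of reelin signalling, 3.76-fold higher (1.91). Ttr read 275 at 4 h, which was 19.0-fold lower than at 1 h (-4.25). In all, 327 probe sets were at least 2-fold higher and 180 at least 2-fold lower, and the balance rested on the scaling, with 209 higher and 235 lower after cyclic loess and 227 higher and 254 lower after quantile normalization.

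Also among the highest ratios at 4 h were Ddx6, an RNA helicase of processing bodies (2.27, with 1.90 and 0.46 on its other probe sets), Nppa, the atrial natriuretic peptide (1.95), Rbm4b, an RNA-binding protein (1.95), and Chek2, a checkpoint kinase of the DNA damage response (1.94). The zinc finger gene Zkscan14 and the Purkinje cell protein gene Pcp2 both stood at 1.89, and Myog, the muscle transcription factor myogenin, at 1.85. At the other end, Ifitm3, an interferon-induced antiviral membrane protein, read 139.7 at 4 h and 474 at 1 h (-1.76). Also low were Ist1, a regulator of the ESCRT machinery (-1.59), Yif1a, a protein of transport between endoplasmic reticulum and Golgi (-1.56), and Rab5c, a GTPase of early endosomes (-1.51). Rprd1b, a binding partner of the RNA polymerase II tail, stood at -1.54, Pigx, an enzyme of glycosylphosphatidylinositol anchor synthesis, at -1.52, and Polr3k, a subunit of RNA polymerase III, at -1.47 with -0.27 on its other probe set. Acaa1b, a peroxisomal thiolase, stood at -1.46 and Abcb10, a mitochondrial transporter, at -1.42. Yif1a (127), Abcb10 (131), Pigx (134) and Rprd1b (138) likewise read close to the floor at 4 h. So did Chek2 (127) and Myog (128) at 1 h.

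The 15 measured cholesterol synthesis genes had a median log2 ratio of -0.41 at 4 h (percentile 0.18), with 11 below and 3 above 0, 1 at least 2-fold lower and 1 at least 2-fold higher. Mvd, which makes isopentenyl pyrophosphate, was at least 2.31-fold lower, and Msmo1, a sterol methyl oxidase, stood at -0.83. Against the direction of the list, Cyp51, the sterol 14-demethylase, read 409.6 at 4 h and 196.5 at 1 h (1.06), and Sc5d, a sterol desaturase, stood at 0.85. Choroid plexus markers again lay lower, with a median of -0.73 (percentile 0.01), 3 of 9 at least 2-fold lower and 0 higher, where Kl stood at -1.13 and Folr1 was at least 2.38-fold lower. Oligodendrocyte and myelin markers (12 measured) had a median of -0.23 (percentile 1.94), with 2 at least 2-fold lower and 10 within 2-fold. These 2 were Gsn, the actin-severing protein gelsolin (-1.24), and Qdpr, which regenerates tetrahydrobiopterin (-1.12), and Mbp, the myelin basic protein, stood at -0.67. The Gapdh ratio of 3' to 5' signal was 5.25 on this array, the highest of the series, and the 3' probe set of 18S ribosomal RNA read 611 against 1530.1 at 1 h. Simulated pairs with probe set scatter alone gave a mean of 233 differences (186 to 266), against 507 observed. Of these 507, 199 higher and 101 lower had both arrays above the floor, where the scatter was gauged. The cholesterol list stayed outside the random range in all 6 other settings, the choroid plexus list did so too but not against the mean of the other arrays (-0.19, percentile 12.5), and the myelin list did so in 4 of 6 and not with random lists matched on gene length (percentile 2.91).

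At 6 h, the array lay nearest to the 1 h array, and the genes furthest apart included several named at 4 h. Btbd3 was 4.37-fold higher than at 1 h (1561 and 357, log2 ratio 2.13), Dab1 3.39-fold (1.76), Ntrk3 3.37-fold (1.75), and Rbm4b 3.23-fold (1.69). Ttr was 27.2-fold lower (192 and 5228.5, -4.76). In all, 176 probe sets were at least 2-fold higher and 115 at least 2-fold lower, with 139 and 151 after cyclic loess and 147 and 153 after quantile normalization. Because the 2, 4 and 6 h arrays were all set against the same 1 h array, a low or high reading on that array enters all 3 ratios of a gene.

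Fancc, a member of the Fanconi anaemia DNA repair pathway, read 3.83-fold higher at 6 h (1.94), with 2.16-fold at 2 h and 1.29-fold at 4 h. Acvrl1, a receptor of the transforming growth factor beta family, stood at 1.84, but at 0.23 and 0.33 on its other probe sets, and Ddx6 at 1.59 with 1.12 and 0.42 on its own. Arl2bp, which binds the small GTPase ARL2, stood at 1.62, Cntnap1, the paranodal axonal protein Caspr, at 1.54, and Atp2b2, a plasma membrane calcium pump, at 1.51. Lower at 6 h were Pcolce, an enhancer of procollagen processing (-1.77), Snx17, a sorting nexin of endosomal recycling (-1.77, with 0.43 on its other probe set), Thyn1 (-1.67, with -0.07), and Hk1, the hexokinase that begins glycolysis in brain (-1.67). Ogfr, the opioid growth factor receptor, stood at -1.58, Rpp30, a subunit of ribonuclease P, at -1.55, Rnh1, the ribonuclease inhibitor, at -1.53 with 0.35 on its other probe set, Efl1, a GTPase of large ribosomal subunit maturation, at -1.48, and Cdc23, a subunit of the anaphase-promoting complex, at -1.46. Efl1 (129.6), Cdc23 (131), Pcolce (138) and Thyn1 (139.8) read close to the floor at 6 h.

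Energy metabolism and translation genes lay slightly lower at 6 h than at 1 h. On the 6 h array the 3' probe set of 18S ribosomal RNA read 641 against 1530.1 at 1 h, and the Gapdh ratio of 3' to 5' signal was 3.78 against 4.31. Oxidative phosphorylation genes had a median of -0.21, below all 10000 random lists, with 49 of 63 members below 0 and 13 above, and all 63 within 2-fold. Atp5k (-0.89) and Atp5mpl (-0.88), small subunits of the ATP synthase, led the list, and Ndufv3, a complex I subunit, stood at -0.78. Ribosomal protein genes had a median of -0.17 (percentile 0.20), with 20 of 29 below 0 and all 29 within 2-fold. The most distant members were Rps29 at 0.90 and Rps13 at -0.71. NF-kappa B targets had a median of -0.31 (percentile 0.76), with all 12 within 2-fold, led by Gadd45b (-0.99) and Relb (-0.73). The 16 glutamate receptor and postsynaptic genes had a median of 0.24 (percentile 98.6), with 2 at least 2-fold higher and 0 lower, and their largest ratios were those of the NMDA receptor subunit gene Grin2d (at least 2.49-fold) and Gria3 (1.00). Choroid plexus markers had a median of -0.31 (percentile 1.44), with 2 of 9 at least 2-fold lower, Ttr and Folr1, and 7 within 2-fold. Simulated pairs gave a mean of 120 differences (99 to 139), against 291 observed. Of these 291, 96 higher and 55 lower had both arrays above the floor, where the scatter was gauged. Oxidative phosphorylation and ribosomal protein lists stayed outside the random range in all 6 other settings and choroid plexus in 5, while NF-kappa B and postsynaptic genes did so in 4 each. With the mean of the other arrays as the reference, ribosomal protein (-0.025, percentile 20.2), choroid plexus (-0.07, percentile 36.2), NF-kappa B (-0.21, percentile 4.44) and postsynaptic (-0.06, percentile 29.2) medians fell inside it, as did ribosomal proteins with random lists matched on gene length (percentile 3.37) and choroid plexus without Ttr (-0.28, percentile 2.57).

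**Figure D2:**
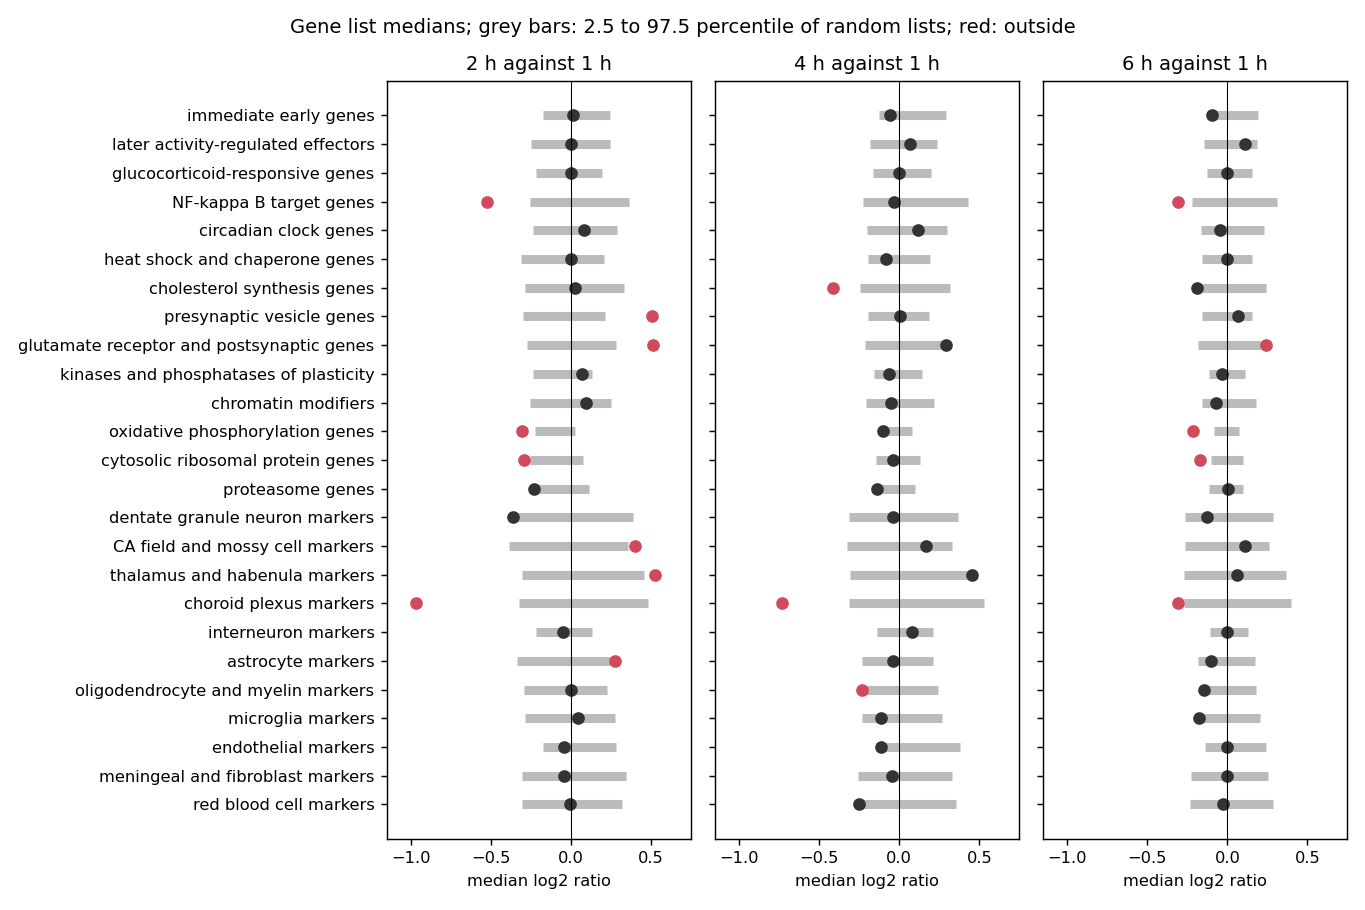
Median log2 ratio of each gene list with at least 5 measured genes at 2, 4 and 6 h against 1 h, with grey bars for the central 95% of 10000 random lists of matched size and signal, and red points for medians outside it. At 2 h, 9 lists lay outside, at 4 h 3 and at 6 h 5.

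Immediate early genes, the transcription factors and regulators that neuronal activity induces within minutes, did not stand apart as a group between 1 h and the later times. Of the 38 genes in the list 26 were measured, and Arc, Npas4, Egr3, Egr4 and Nr4a3 were not among them. The median log2 ratio over the 26 measured members was 0.01 at 2 h (percentile 56.5), -0.06 at 4 h (percentile 9.14) and -0.09 at 6 h (percentile 3.81). At 2 h 2 members were at least 2-fold higher, 1 was at least 2-fold lower and 23 were within 2-fold, at 4 h all 26 were within 2-fold, and at 6 h 1 was higher, 1 lower and 24 within 2-fold. Fosl2 and Ccn1 lay under the floor at both 1 and 4 h, so their log2 ratio at 4 h was set to 0. Fos, the AP-1 subunit used as a marker of recent neuronal activity, read 333, 201, 225 and 169.5 at 1, 2, 4 and 6 h. Egr1, the zinc finger factor Zif268, read 1285, 1158.5, 933 and 817, and Nr4a1, an orphan nuclear receptor, 422, 237, 349 and 335.5. Gadd45b read 406, 154, 325 and 204, which put it at -1.40 at 2 h, and Ppp1r15a, which directs dephosphorylation of eIF2 alpha, stood at -1.05 at 6 h. In the other direction, Mafk, a small Maf factor, stood at 1.30 at 2 h, Atf3, a stress-induced factor, at 1.14 at 2 h, and Zfp36, which destabilises cytokine mRNAs, at 1.03 at 6 h. Junb, Jun and Btg2 stayed within 2-fold of their 1 h signal on every later array. Later activity-regulated effectors (18 measured) had medians of 0.00, 0.06 and 0.11 at 2, 4 and 6 h, all inside the random range. Nptx1, the secreted neuronal pentraxin that clusters AMPA receptors, read 4132 at 2 h and 1425 at 1 h (1.54), the prohormone convertase gene Pcsk1 was at least 2.05-fold higher at 6 h, Rgs2, a regulator of G protein signalling, stood at -0.87 at 2 h, and Bdnf, the neurotrophin, stood at 0.43 at 6 h.

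**Figure D3:**
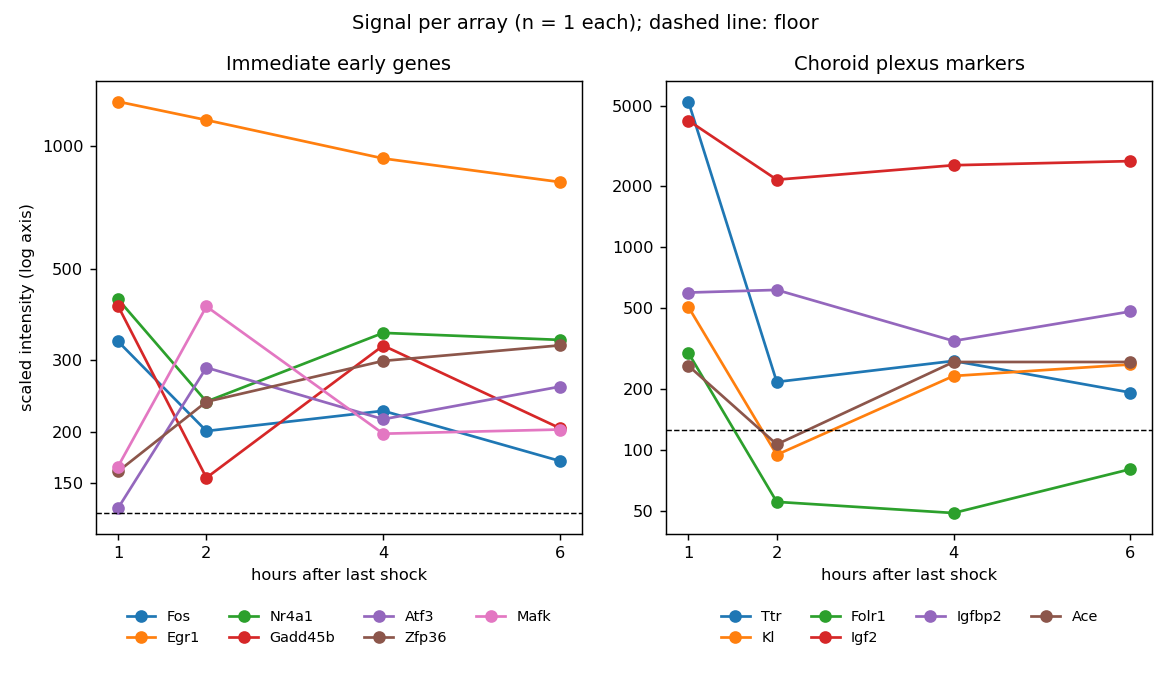
Scaled intensity (log axis) against hours after the last shock for 7 immediate early genes (left) and 6 choroid plexus markers (right), with 1 array per point and a dashed line at the floor of 126. Ttr went from 5228.5 at 1 h to 217, 275 and 192, and Fos from 333 to 201, 225 and 169.5.

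Stress-hormone, clock and chaperone genes stayed inside the random range as groups at all 3 times, with single members past 2-fold. Glucocorticoid-responsive genes (25 measured) had a median of 0.00 at each time. Sgk1, the serum and glucocorticoid kinase, stood at -1.43 at 2 h and -0.95 at 6 h, Fkbp5, the co-chaperone of the glucocorticoid receptor, at 1.09 at 2 h, and Ddit4, an inhibitor of mTOR signalling, at -1.33 at 4 h. Circadian clock genes (16 measured) had medians of 0.08, 0.12 and -0.04. Cry2, a repressor of the clock, read 142 at 1 h, 517 at 2 h, 396 at 4 h and 251.5 at 6 h (log2 ratios 1.86, 1.48 and 0.82). Per3 stood at 1.22 at 4 h, and Dbp, an output factor of the clock, at -1.11 at 2 h. Heat shock and chaperone genes (19 measured) had medians of 0.00, -0.08 and 0.00, with Hspa1l, an Hsp70 family member, at least 2.52-fold higher at 4 h from a 1 h signal under the floor, Hspd1, the mitochondrial chaperonin, at -0.91 at 4 h and Hmox1, heme oxygenase, at 0.87 at 2 h.

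Plasticity kinases and phosphatases (26 measured) had medians of 0.06, -0.06 and -0.03. Cdk5r1, the p35 activator of CDK5, was at least 2.52-fold, 1.66-fold and 2.27-fold higher at 2, 4 and 6 h from a 1 h signal under the floor. Ppp1cb, a catalytic subunit of protein phosphatase 1, stood at -1.08 at 4 h and Fyn, a Src family kinase, at -0.80 at 2 h. Chromatin modifiers (22 measured) had medians of 0.09, -0.05 and -0.07. Among them, Kat2a, the histone acetyltransferase GCN5, was at least 5.24-fold lower at 2 h and at 4 h, where its signal lay under the floor, and stood at -0.72 at 6 h. Hdac2, a histone deacetylase, stood at -1.20 at 4 h, and Kdm6a, a histone demethylase, at 1.07 at 4 h. Proteasome genes (38 measured) had medians of -0.23, -0.14 and 0.01. Psmb6, a catalytic core subunit, read 2025 at 1 h and 917, 928 and 945 at 2, 4 and 6 h, whereas Psmd3, a subunit of the regulatory lid, stood at 1.51 at 2 h.

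Dentate granule neuron markers (8 measured) had medians of -0.36, -0.04 and -0.13 at 2, 4 and 6 h and stayed inside the random range. At 2 h they lay just inside its lower end (percentile 2.63), with 6 members below and 2 above 0. Prox1, a transcription factor of granule neurons, was at least 1.81-fold higher at 2 h and under the floor at 1, 4 and 6 h, Neurod1, a neuronal differentiation factor, stood at -0.84 at 2 h, Npnt, nephronectin, at -0.79 at 6 h, and Tdo2, tryptophan dioxygenase, at 0.60 at 4 h. Interneuron markers (17 measured) had medians of -0.05, 0.08 and 0.00, with the homeobox gene Dlx1 at least 2.01-fold lower at 2 and 4 h, the serotonin receptor gene Htr3a at 0.77 at 4 h and the parvalbumin gene Pvalb at 0.64 at 2 h. Microglia markers (12 measured) had medians of 0.04, -0.11 and -0.18, with Fcgr3, an Fc receptor, at least 2.02-fold higher at 4 h from a 1 h signal under the floor, and C1qa, a complement subunit, at 0.53 at 2 h and -0.85 at 4 h. Endothelial markers (14 measured) had medians of -0.04, -0.12 and 0.00, with the glucose transporter gene Slc2a1 at least 2.18-fold and the smooth muscle actin gene Acta2 at least 2.04-fold lower at 4 h, and Eng, endoglin, at -1.04 at 2 h. Meningeal and fibroblast markers (13 measured) had medians of -0.04, -0.04 and 0.00, with the prostaglandin synthase gene Ptgds at -1.09 at 2 h, the complement inhibitor gene Serping1 at 0.98 at 6 h and Islr at 0.91 at 2 h. Red blood cell markers (6 measured) had medians of 0.00, -0.25 and -0.03, with Bpgm, a phosphoglycerate mutase, at -0.88 at 4 h and the haemoglobin gene Hba-a1 at -0.51 at 6 h. Only 2 of the sex-linked genes were measured, Eif2s3y and Uty, both on the Y chromosome and both above the floor at 1, 2 and 6 h. At 4 h both lay below their 1 h level (median log2 ratio -0.45). Between 4 and 1 h, CA field markers (median 0.17), thalamus markers (0.45), astrocyte markers (-0.04), presynaptic genes (0.00), postsynaptic genes (0.29), NF-kappa B targets (-0.03), oxidative phosphorylation genes (-0.10) and ribosomal protein genes (-0.04) stayed inside the random range. Between 6 and 1 h so did presynaptic genes (0.07), cholesterol synthesis genes (-0.19), CA field markers (0.11), thalamus markers (0.06), astrocyte markers (-0.10) and myelin markers (-0.14), and between 2 and 1 h so did cholesterol synthesis (0.02) and myelin (0.00) genes. Over the 75 list comparisons 17 lay outside the range, where 3.75 would by construction if list genes behaved as random genes do.

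Set against the preceding time point, the 4 h array had 280 probe sets at least 2-fold higher and 446 at least 2-fold lower than the 2 h array, but 1157 higher and 1031 lower with the floor at the 20th percentile and 1167 and 1146 at a threshold of 1.5-fold. The 6 h array had 188 at least 2-fold higher and 262 at least 2-fold lower than the 4 h array, a balance that rested on the scaling, with 220 and 219 after quantile normalization and 205 and 215 after cyclic loess. Between 2 and 4 h, Kif5a went from 1339.9 to 219, Syt11 from 2710 to 639, and Tradd from 229.8 to 825. Between 4 and 6 h, Pcp2 went from 757 to 233, Nppa from 595 to 226 and Ifitm3 from 139.7 to 386.

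More probe sets stood at least 2-fold above all other arrays at 2 h than at any other time, except with the floor at the 20th percentile, where the 4 h array had 393 and the 2 h array 296. The 2 h array had 162 above and 29 below all others, the 4 h array 58 above and 39 below, the 1 h array 14 above and 45 below, and the 6 h array 15 above and 27 below. After quantile normalization the 1 h array had 20 above and 37 below and the 4 h array 41 above and 46 below. Among named genes above the floor on all arrays, Ttr lay furthest above the others at 1 h, and Kif5a, Syt11 and Grik5 at 2 h. Btbd3, Ddx6, Rbm4b, Zkscan14, Atp2b2 and Acvrl1 were among those at least 2-fold below all other arrays at 1 h. Without the 2 h array, the 1 h array had 35 above and 73 below.

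Few genes moved steadily in one direction through the series. Above the floor on every array, 23 probe sets had a higher signal at each successive time and 9 a lower one, with at least 2-fold between 1 and 6 h. These were 13 and 14 after cyclic loess, and 15 and 13 after quantile normalization. A linear trend on hours over the 4 arrays, fitted with limma on 2 residual degrees of freedom after the data had been seen, called 0 of 6109 probe sets at a Benjamini-Hochberg adjusted threshold of 0.05 (smallest adjusted p = 1). At an unadjusted threshold of 0.05 it called 151, where 305.4 would be by chance. With 1 array per time, any departure from a straight line counts as error in this fit. The low counts therefore do not show a lack of change. Cntnap1 read 163, 252, 425 and 473, Daglb, a diacylglycerol lipase that makes an endocannabinoid, 181, 296, 405 and 477, and Pdia3, a disulphide isomerase of the endoplasmic reticulum, 222, 252, 468 and 541.5. Tle3, a Groucho family corepressor, read 343, 421, 591 and 834, and St8sia5, a sialyltransferase of gangliosides, 256, 436, 481 and 611. Downward went Mms19, an iron-sulphur cluster assembly factor (393, 379.5, 177 and 157), Pold4, a DNA polymerase delta subunit (326, 161.3, 161.2 and 135), and Rcor1, the corepressor CoREST (348, 265, 224 and 158). Gjb6, the astrocyte connexin 30, read 665, 636, 470.2 and 327, and stood at -0.31 at 6 h against 1 h on the only other of its probe sets above the floor. Id1, an inhibitor of basic helix-loop-helix factors, read 358, 285, 228 and 177.

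Different probe sets of the same gene gave weakly related ratios. Across genes with both probe sets above the floor, their log2 ratios correlated at r = 0.17 at 2 h (766 genes), 0.08 at 4 h (746 genes) and 0.02 at 6 h (746 genes), and had the same sign in 57.7%, 55.0% and 50.5%, where genes are not independent replicates. Of 30 genes at least 2-fold higher at 2 h that had a further probe set above the floor, 18 had the same direction on it and 3 passed 2-fold there. Of 11 lower genes 5 had the same direction and 2 passed 2-fold. At 4 h these were 9 and 1 of 10 higher genes and 4 and 0 of 9 lower genes. At 6 h they were 7 and 2 of 11 higher genes and 5 and 1 of 9 lower genes.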

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

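The settings without the 2 h array, with the mean of the 3 other arrays as the reference, without Ttr and with random lists matched on gene length, and the linear trend, were chosen after seeing the data. The trend called 0 probe sets at the adjusted threshold under each of the 5 other scalings and floors too, and between 84 and 280 at the unadjusted one. No paired analysis was possible because each time point has 1 array. Counts of probe sets depended on the floor and on the threshold by construction, since a lower floor admits dim probe sets and a lower threshold admits smaller differences, and a ratio against a signal under the floor is only a lower bound. Leaving the deposited scale untouched kept all 20 counts within 1.5 times the main count, quantile normalization 19 and cyclic loess 17, where 4 against 1 h went from 327 to 209 higher under loess, and steady courses from 23 to 13 rising and from 9 to 14 falling under loess and from 23 to 15 rising under quantile normalization. With the floor at the 20th percentile, 1000, 1264 and 854 probe sets were higher and 667, 737 and 639 lower at 2, 4 and 6 h against 1 h, 1157 higher and 1031 lower at 4 against 2 h, and 870 higher and 1124 lower at 6 against 4 h. At that floor 109, 296, 393 and 180 stood above and 176, 155, 223 and 189 below all other arrays at 1, 2, 4 and 6 h, and 78 had a rising and 48 a falling course. With the floor at the 60th percentile, 176, 67 and 37 were higher and 52, 47 and 12 lower against 1 h, 59 higher and 183 lower at 4 against 2 h, and 19 higher and 30 lower at 6 against 4 h. There 3, 79, 4 and 0 stood above and 12, 8, 4 and 2 below all others, with 5 rising and 1 falling. At a threshold of 1.5-fold, 1263, 1191 and 814 were higher and 855, 734 and 570 lower against 1 h, 1167 higher and 1146 lower at 4 against 2 h, and 738 higher and 955 lower at 6 against 4 h. In this setting 113, 451, 332 and 124 stood above and 226, 239, 199 and 121 below all others, with 93 rising and 55 falling. At 3-fold, 98, 51 and 20 were higher and 16, 25 and 17 lower against 1 h, 29 higher and 116 lower at 4 against 2 h, and 18 higher and 38 lower at 6 against 4 h. At that threshold 4, 36, 6 and 3 stood above and 5, 3, 3 and 0 below all others, with 0 rising and 1 falling. Without the 2 h array, 35, 100 and 43 stood above and 73, 60 and 43 below all others at 1, 4 and 6 h, with 58 rising and 34 falling, since fewer arrays then have to be passed. The 2 h array had the most probe sets standing above all others in every setting that held it, except with the floor at the 20th percentile, where the 4 h array had 393.

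Of the 17 list medians outside the random range, 8 stayed outside under all 6 settings fixed in advance. For the others the values inside the range were as follows, and the cause was not tested except where a setting removes genes or arrays. NF-kappa B targets had -0.0812 at the 20th percentile floor and -0.14 over all probe sets at 2 h, and -0.11 and -0.18 at 6 h. Ribosomal protein genes at 2 h had -0.12 under quantile normalization, -0.0109 under loess, -0.20 at the 20th percentile floor and -0.19 over all probe sets. Postsynaptic genes at 6 h had 0.24 at the 20th percentile floor and 0.15 at the 60th. Thalamus markers at 2 h had 0.37 at the 20th percentile floor, 0.19 at the 60th and 0.37 over all probe sets, CA field markers 0.39 under loess and 0.19 at the 20th percentile floor, and astrocyte markers 0.16 over all probe sets. At 4 h, myelin markers had -0.23 at the 20th percentile floor and -0.0454 over all probe sets, and choroid plexus markers at 6 h had -0.32 under quantile normalization. Against the mean of the 3 other arrays, the postsynaptic median at 6 h changed sign to -0.0595, and medians fell inside the range for NF-kappa B targets at 6 h (-0.21), oxidative phosphorylation at 2 h (-0.16), ribosomal proteins at 2 h (-0.11) and 6 h (-0.025), CA field (0.12) and thalamus markers (0.27) at 2 h, and choroid plexus at 4 h (-0.19) and 6 h (-0.0656). With random lists matched on gene length, ribosomal proteins at 6 h (-0.17, percentile 3.37) and myelin at 4 h (-0.23, percentile 2.91) came inside, and so did choroid plexus at 6 h without Ttr (-0.28). In the opposite sense, 35 of the repeats of medians inside the range moved outside it. Repeats of the log2 ratios against 1 h of the genes that the naming rule takes (426 ratios, with the 4 largest of each list) numbered 2130, of which 2015 kept their sign, 108 became 0 with the floor at the 60th percentile and 7 changed sign, all 7 of ratios within 2-fold. By more than the scatter of a probe set 192 moved, 156 at that floor and 36 with the floor at the 20th percentile.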

Other observations

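Each array was also set against the mean of the other arrays, a comparison chosen after seeing the data, as was the picking of the genes in this paragraph. Of 100 such medians 22 lay outside the random range, where 5.0 would by chance, and the medians of a list on the 4 arrays are not independent. On the 1 h array, NF-kappa B targets (median log2 ratio 0.34, percentile 99.8 among random lists), cholesterol synthesis (0.22, percentile 98.3), oxidative phosphorylation (0.22, above all random lists) and ribosomal protein genes (0.17, percentile 99.1), choroid plexus markers (0.35, percentile 99.5) and endothelial markers, genes of blood vessel lining (0.13, percentile 97.8), were higher, and presynaptic (-0.28, percentile 0.02) and postsynaptic genes (-0.45, percentile 0.01) and CA field markers (-0.30, percentile 1.36) lower. On the 2 h array, presynaptic (0.48, percentile 99.99) and postsynaptic genes (0.46, percentile 99.98), plasticity kinases and phosphatases (0.13, percentile 98.5) and astrocyte markers (0.24, percentile 98.8) were higher, and NF-kappa B targets (-0.33, percentile 0.65) and choroid plexus markers (-0.50, percentile 0.06) lower. On the 4 h array, thalamus and habenula markers were higher (0.48, percentile 99.5), and cholesterol synthesis genes (-0.30, percentile 0.71) and myelin markers (-0.17, percentile 1.53) lower. On the 6 h array, endothelial markers were higher (0.25, percentile 99.4), where Cldn5, the tight junction claudin, read 579.8 against 363 at 1 h, and plasticity kinases and phosphatases (-0.12, percentile 0.91), oxidative phosphorylation genes (-0.09, percentile 0.14) and astrocyte markers (-0.14, percentile 2.36) were lower.

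Some genes stood apart on a single array and are given here as values picked for their size. Scn8a, a voltage-gated sodium channel, read 262, 1059, 271 and 359.6 at 1, 2, 4 and 6 h, and Epha7, an ephrin receptor, 2113, 942, 1989.7 and 2169. Cacna2d1, a calcium channel subunit, read 258.5, 758.5, 689.6 and 708. Dhodh, an enzyme of pyrimidine synthesis, read 643, 1392, 1125 and 242, and Txnrd3, a thioredoxin reductase, 1357, 1739.6, 1675.5 and 618. The probe sets of Dhodh, Txnrd3, Igf2 and Aqp1 carry identifier suffixes of shared probes or relaxed rules.

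Except for the comparison of steady courses with other orders of the arrays, all tests in the next paragraphs were chosen only after the result was seen. The synaptic lists were higher on the 2 h array, the same array whose Gapdh and Actb controls had more 5' signal. A bias by genomic span is argued against, since the lower of the 2 list percentiles was 99.99 among random lists matched on span. Span was nearly unrelated to the ratio at 2 h across genes (Spearman's rho -0.04). Genomic span only approximates transcript length, which was not tested. A larger share of neurons in that sample stays open. For this test 21 abundant genes of the synaptic and kinase lists were chosen by their signal at 4 and 6 h. Their median log2 ratio was -0.15, with 9 genes above and 12 below 0. It lay 0.0504 above that of 636 other abundant genes (-0.20). The 95% bootstrap interval of -0.08 to 0.35 holds the bound of 0.25 set for the test. Members of the synaptic lists are among the 21, so the test is not independent of the pattern. Uneven signal along transcripts stays open too. The test took the SD of the difference between probe sets of a gene, against 1 h. It asked for an SD at 2 h over 1.2 times that of the reference array, with an interval above 1. The SD at 2 h was 1.337 times that at 6 h (interval 1.24 to 1.44, 702 genes), which met this. The SD at 2 h was 1.1395 times that at 4 h (interval 1.05 to 1.23, 700 genes), which did not. A noisier 2 h array would also give a larger SD. A biological difference at 2 h stays open and untested, because time point and array are the same thing here.

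The choroid plexus markers were higher on the 1 h array than later, led by Ttr. A candidate source is choroid plexus tissue carried into the 1 h dissection. Without Ttr the other 8 markers still had medians of -0.77, -0.61 and -0.28 at 2, 4 and 6 h, but the highest percentile, 2.57 at 6 h, came just inside the random range, so the test leaves the source open. Of the 9 markers 5 were lower than at 1 h at all 3 times (Ttr, Kl, Folr1, Igf2 and Slc4a2), and the other 4 were higher at 1 time or more, among them Ace, which read 261 at 1 h, 107 at 2 h (under the floor) and 272 at both 4 and 6 h, and Aqp1, which read 121 at 1 h (under the floor) and 221 at 2 h. A difference between 1 h and later in the tissue itself cannot be told apart from this with 1 array per time point.

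Probe sets with a steady course from 1 to 6 h numbered 32. The other order of the arrays that begins with 1 h and ends with 6 h gave 28, and 2 orders are too few for a share under 0.05. The comparison planned in advance was with all 12 orders, and the restriction to those with the same ends came after the data had been seen. The 10 orders with other ends gave 43 to 119. They are no fair comparison, because a steady course needs 2-fold between its ends and other pairs of arrays differed more. Over 6109 probe sets above the floor on every array, 5.52% had the same direction at each step, where 8.33% would if the arrays were exchangeable.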
